A study of Mus musculus with 8 samples.

How the data were processed

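The series measured total RNA of the left ventricle of male mice in 8 libraries, 2 mice per group, for MI and sham surgery at 1 and 3 days. Per the labels' protocols, tissue RNA was extracted with a column kit, depleted of ribosomal RNA and sequenced in pairs on an Illumina instrument. Per the submitters' processing notes, the tools FastQC, Bowtie2 2.2.5, TopHat2 2.0.14, SAMtools 0.1.2, HTSeq and DESeq2 and the build mm10 were used, with no role or order given. The annotation release, the strand setting and any filter of the counting are not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart.

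The deposited count tables, 1 per time point, hold raw read counts per gene symbol, with whole numbers per the file headers and values. Count columns name the group but not the replicate, and 2 columns of the sham group at 1 day carry the same name in the header, so the libraries were named A and B by column order within a group. The authors also deposited 1 DESeq2 table per time point with a log2 fold change, its standard error, a p-value and an adjusted p-value, per the file headers. Comparison with the counts showed that the sign is MI over sham at 1 day and sham over MI at 3 days. The third kind of file, called TE in its name, is a transcript expression table, per the file headers: counts of unique and total reads per transcript, RPKM, transcript length, and a test named EDGE with a signed fold change and an FDR-corrected p-value. The design of the tests had assumed that these tables might hold repeat elements; as they do not, transcripts were summed to genes in place of repeat groups. RPKM values were not used here. The software behind these tables is not given in the sources used here.

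Both count tables were joined by symbol, which left 24062 genes in both. Genes with low counts were removed with edgeR's filterByExpr over the 4 groups, which left 15508 tested and 8554 not tested. Counts were normalised by the TMM method, and CPM values use these effective library sizes. All 8 libraries were fitted together by group in edgeR 4.0.16 under R 4.3.3 (robust quasi-likelihood fit, legacy option off, common dispersion 0.0602, median prior degrees of freedom 5.51, and 4 residual degrees of freedom). Sharing 1 estimate of the spread was chosen because 2 against 2 libraries leave few degrees of freedom. The 2-sided quasi-likelihood F test was applied to MI against sham at each day, to the difference of these effects, and to 3 days against 1 day within each surgery. P-values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. The SE of a log2 fold change is its size divided by the square root of F.

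Gene lists were fixed before the data were examined: 14 main lists and 21 others, of pathways, complexes and cell types. Of these 35, 33 had at least 5 tested members and were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, 2-sided, adjusted over the lists. For each list, the members past the gene test were counted, also with p-values adjusted over the list alone. Counts were repeated with each library left out, and those that moved by more than 1.5 times are given, except counts of 1 or 2 members that moved by 1 or 2. None of the calls held when camera estimated the correlation: 0 of 14 at 1 day, 0 of 17 at 3 days and 0 of 15 for the difference. The directional test fry, which asks if the genes of a list move on balance 1 way and does not compare them with other genes, kept 41 of these 46 calls. The list of mitochondrially encoded genes had 0 members in the count tables and was read in the transcript tables. List genes absent from the tables, among them Adgre1, Ly6g and Mhrt, were not analysed here.

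The genes named were set by a rule. At each day these were the 3 largest rises and the 3 largest falls among called genes with a mean of at least 5 CPM, both MI libraries beyond both sham libraries and no predicted-gene symbol. To these were added the 2 called members with the largest change in each main list (or, with none called, the member with the highest mean), the top called member of each other list that passed camera, and always Nppa, Nppb, Myh6, Myh7, Il6 and Postn. For the difference, the 5 most positive and 5 most negative called genes were named, and for the contrasts of 3 days with 1 day and the transcript tables the 3 at each end. A result of 1 gene chosen by the rule is not reported here. Gene positions come from a RefSeq table of GRCm38.p6, the assembly of mm10. A reference genome of another build, NCBIM37, was not used.

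Transcript reads of 96535 transcripts were summed to 31165 genes and tested like the genes, with library sizes and TMM factors from the gene counts; 14571 genes were tested. Mitochondrial shares are percentages of all transcript-table reads of a library (8.55 × 10⁶ to 13.27 × 10⁶), with exact Clopper-Pearson 95% intervals. In comparisons of 2 groups in the count tables, a named gene with 1 to 3 counts in a group is given as a ratio with an exact interval, and list medians were also computed with such genes at the bound of their interval nearest to no change. The floor for a count of 0 is 3 counts over the group.

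The code was tested on simulated counts drawn with the means, dispersions and library sizes of the real genes, with 200 genes changed by known folds. The changed genes were drawn from those with a mean of at least 1 CPM. On 15508 simulated genes the 1-day test recovered 2, 12, 92 and 88% of changes of 1.5, 2, 4 and 8-fold, with 0% false among all calls. The 3-day test recovered 4, 26, 76 and 96%, with 9.82% false, and the test of the difference 14, 56, 92 and 96%, with 5.84% false. In both kinds of table the simulated genes changed in opposite directions at 1 and 3 days. The fold of their difference was thus the square of the fold named, and its recovery cannot be compared with that of single days. On 14571 simulated genes of the transcript tables, recovery was 0, 24, 96 and 94% at 1 day, 2, 30, 84 and 100% at 3 days and 20, 66, 100 and 100% for the difference, with 5.31, 8.47 and 10.1% false. Both shifted lists were called in the right direction and 0 of the other 31 lists. Simulated genes were drawn independently of each other, so this cannot show how often lists of correlated genes are called falsely. In the real data 6051 genes were called at 1 day and 8591 at 3 days, far more than the 200 changed here. Normalisation and adjustment thus worked under other conditions, and these rates check the code but do not give the recovery or false calls of the real tests.

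Alternatives set in advance were DESeq2's size factors, library size alone, no filter beyond 1 count, a filter of at least 1 CPM in 4 libraries, the Wald test of DESeq2 1.42.0, limma-voom, edgeR's legacy option, the 4 libraries of a time point alone, changes of at least 2-fold, an estimated correlation and fry for the lists, single transcripts and own library sizes for the transcript tables, and each library left out in turn. A group left with 1 library was assumed to vary like the other groups. The low-count filter was rerun with each library left out, which changed the number of genes tested. Alternatives added after the data were seen left out both B libraries of day 1, or mitochondrially encoded genes in the transcript tables. With 2 mice per group no exact permutation test can pass 0.05, so tests rest on the model across genes.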

Results

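Total RNA from the free wall of the left ventricle was sequenced in male C57BL/6 mice after myocardial infarction (MI), induced by ligating the left anterior descending coronary artery, or after sham surgery. Tissue was taken 1 day or 3 days after surgery, from 2 mice in each of 4 groups, so that each time point had its own sham controls. The libraries of a group are called A and B in the order of the count columns, which carry no replicate number. The sham libraries held 20.68 × 10⁶ and 20.12 × 10⁶ gene counts at 1 day and 18.83 × 10⁶ and 19.85 × 10⁶ at 3 days. The MI libraries held 12.66 × 10⁶ and 7.38 × 10⁶ counts at 1 day and 21.06 × 10⁶ and 25.04 × 10⁶ at 3 days. At these depths 3 counts equalled 0.102 to 0.369 CPM (counts per 10⁶ counts) in a library. Levels are given as mean CPM ± SD (n = 2), and fold changes of MI against sham on the log2 scale with the standard error (SE) of the fit.

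Some measures of the libraries moved with the groups. Sample numbers in the deposited column names lay close within a group and apart between MI and sham, furthest at 1 day. Whether the groups were prepared or sequenced apart is not given in the sources used here. A batch that coincided with MI could not be told apart from MI on either day or in the difference. Genes encoded by mitochondrial DNA took 15.04% (95% exact binomial interval 15.02 to 15.06) and 13.88% (13.86 to 13.90) of the transcript-table reads in the sham libraries A and B at 1 day. They took 28.70% (28.67 to 28.73) and 43.34% (43.30 to 43.37) in the MI libraries A and B at 1 day. At 3 days the shares were 16.56% (16.54 to 16.58) and 15.68% (15.65 to 15.70) after sham surgery, and 6.51% (6.49 to 6.52) and 4.19% (4.18 to 4.20) after MI. Of 1495 chemosensory receptor genes, a set named by symbol after the counts were seen, MI library B at 1 day held reads for 92.0%. The share was 50.6% in sham library B and 23.5% in MI library A at 1 day, 5.22% in sham library A, and 4.28 to 8.09% in the 4 libraries of 3 days. These intervals, and the limits given for genes with few counts, cover counting error alone. The Spearman correlation between the 2 libraries of a group, across genes, which are not independent replicates, was 0.954 for MI at 1 day and 0.981 to 0.992 for the other groups.

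**Figure D1:**
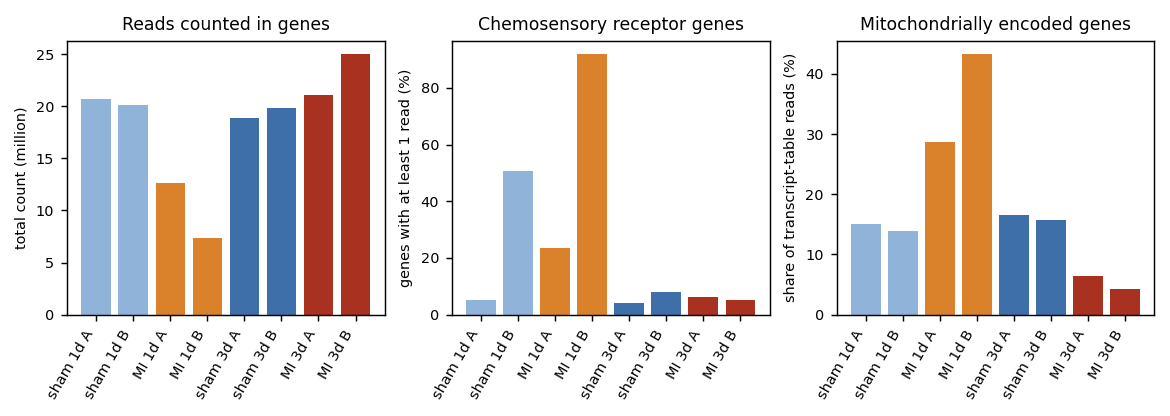
Bars show, for each of the 8 libraries, the gene counts in units of 10⁶, the share of 1495 chemosensory receptor genes with at least 1 read in percent, and the share of transcript-table reads from mitochondrially encoded genes in percent. MI library B at 1 day had the lowest total (7.38 × 10⁶), the highest receptor share (92.0%) and the highest mitochondrial share (43.3%).

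The comparison of infarcted with sham-operated ventricle at 1 day asks which RNAs had changed early after the injury. Genes of inflammation were far higher after MI, and genes of cardiomyocyte metabolism and excitation were lower. Il6 (Ensembl ENSMUSG00000025746, chromosome 5, 30013114 to 30019975 in GRCm38.p6), which encodes an inflammatory cytokine, was at 0.288 ± 0.162 CPM after sham surgery and 144 ± 61.8 CPM after MI. Its log2 fold change was 8.94 (SE 0.76, adjusted p = 0.000108). The chemokine gene Cxcl2, whose product attracts neutrophils, rose from 0.289 ± 0.0833 to 159 ± 123 CPM, a log2 fold change of 9.08 (SE 1.87, adjusted p = 0.00492). Asb2 (Ensembl ENSMUSG00000021200, chromosome 12, 103321142 to 103356001 in GRCm38.p6), a muscle gene for a subunit of a ubiquitin ligase, fell from 824 ± 108 to 74.4 ± 8.15 CPM, a log2 fold change of −3.47 (SE 0.19, adjusted p = 3.49e-05). The other genes with the largest falls were Lingo3, at −3.52 (SE 0.36, adjusted p = 0.000195), and Itgb6, an integrin subunit, at −3.41 (SE 0.50, adjusted p = 0.00102). Cxcl3, another neutrophil attractant, had 2 counts in the sham libraries and 3285 in the MI libraries, a ratio of 2782 with a counting interval from 769.6 to 22984. The call on Cxcl2 was lost without sham library A (adjusted p = 0.0741), sham library B (0.0730) or MI library A (0.0681) and with limma-voom (0.273), which also lost Cxcl3 (0.107).

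By the edgeR quasi-likelihood test, 2993 genes rose and 3058 fell among 15508 tested at 1 day (Benjamini-Hochberg adjusted p, threshold 0.05). Of these, 2290 rose and 1831 fell by at least 2-fold. The number of changed genes, 6051, became 2688 without sham library A, 2940 without sham library B and 9388 without MI library A. The low-count filter was rerun in these fits, which tested 17982, 17786 and 17840 genes in this order. Normalising to library size alone raised the median of all genes by 0.28 on the log2 scale and gave 4278 rises and 2025 falls, 67.9% upward against 49.5%.

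Genes of contraction and excitation fell at 1 day. Of 25 sarcomere genes, 17 fell (18 adjusted over the list alone, with 1 rise) and the median log2 fold change was −0.74. Myh6, the main myosin heavy chain of the adult mouse ventricle (Ensembl ENSMUSG00000040752, chromosome 14, 54941921 to 54968017 in GRCm38.p6), fell from 35947 ± 1881 to 12262 ± 5601 CPM, a log2 fold change of −1.55 (SE 0.29, adjusted p = 0.00292). Mylk3, the cardiac myosin light chain kinase, stood at −2.10 (SE 0.17, adjusted p = 9.83e-05) and Myh7b at −2.91 (SE 0.41, adjusted p = 0.000837). Of 27 genes of calcium handling and ion channels, 22 fell (23 adjusted over the list alone), with a median of −1.36. Examples were the potassium channel genes Kcnip2, at −2.33 (SE 0.30, adjusted p = 0.000529), and Kcnj11, at −2.19 (SE 0.20, adjusted p = 0.000148). The limma camera test gave adjusted p = 7.71e-06 for the sarcomere list and 1.07e-08 for the channel list. With an estimated correlation these became adjusted p = 0.343 and adjusted p = 0.195. The sarcomere count was 9 without sham library A and 11 without sham library B.

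Genes of mitochondrial energy metabolism encoded in the nucleus also fell at 1 day. Of 51 respiratory chain genes, 48 fell, also when adjusted over the list alone, with a median of −1.02. Ndufs7 and Ndufa8, subunits of complex I, changed by −1.94 (SE 0.25, adjusted p = 0.000580) and −1.73 (SE 0.30, adjusted p = 0.00222). Of 23 genes of the citric acid cycle and pyruvate dehydrogenase, 21 fell (23 adjusted over the list alone), with a median of −1.04, among them Dlat at −1.63 (SE 0.25, adjusted p = 0.00117) and Ogdh at −1.53 (SE 0.21, adjusted p = 0.000721). Of 28 genes of fatty acid uptake and oxidation, 20 fell and 1 rose (23 and 1 adjusted over the list alone), with a median of −0.77. Ppara, a transcription factor of fatty acid oxidation, fell to 59.9 ± 31.0 from 209 ± 12.7 CPM, a log2 fold change of −1.78 (SE 0.34). The gene that rose was Pdk4, a kinase that inhibits pyruvate dehydrogenase, from 635 ± 249 to 1967 ± 484 CPM, a log2 fold change of 1.63 (SE 0.28, adjusted p = 0.00195). The camera test gave adjusted p = 6.07e-14, 1.07e-08 and 7.71e-06 for the 3 lists in this order, and adjusted p = 0.343 for each with an estimated correlation. The share of reads from mitochondrially encoded genes was higher in the same MI libraries, at 28.7% and 43.3%. Of 25 cardiac transcription factors and mitochondrial regulators, 16 fell and 1 rose, also when adjusted over the list alone (median −0.78, camera adjusted p = 7.52e-05, and adjusted p = 0.343 with an estimated correlation). Perm1, a regulator of mitochondrial genes in muscle, changed by −2.28 (SE 0.23, adjusted p = 0.000212).

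Cytokine genes and markers of neutrophils rose at 1 day. Of 36 cytokine and chemokine genes, 27 rose and 1 fell (28 and 1 adjusted over the list alone), with a median of 4.36, or 3.89 with the 6 members of 3 counts or fewer set to their counting bounds. Of 24 neutrophil markers, 23 rose, also when adjusted over the list alone, with a median of 3.90, or 3.75 with 1 such member at its bound. Trem1, a receptor that amplifies inflammation, changed by 6.00 (SE 0.49, adjusted p = 0.000110), and Cd177, a surface protein of neutrophils, rose from 1.76 ± 0.949 to 108 ± 41.8 CPM, or 5.94 (SE 0.54, adjusted p = 0.000148). Camera adjusted p was 1.07e-08 for the cytokines and 3.43e-10 for the neutrophil markers, and adjusted p = 0.343 for both with an estimated correlation. Of the cytokine genes, 15 rose without sham library A and 17 without sham library B. Without MI library B, which had reads in 92.0% of receptor genes, 23 cytokine genes and 23 neutrophil markers rose.

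Markers of monocytes and recruited macrophages rose at 1 day. Of 25 such markers, 16 rose and 1 fell (18 and 3 adjusted over the list alone), with a median of 2.09. Arg1, the arginase of alternatively activated macrophages, rose from 2.50 ± 2.64 to 300.3 ± 43.1 CPM, or 6.90 (SE 0.59, adjusted p = 0.000117), and Chil3 changed by 6.06 (SE 0.58, adjusted p = 0.000176). Camera adjusted p was 0.000145, and adjusted p = 0.526 with an estimated correlation. Of 22 matrix metalloproteinases and genes of the plasminogen system, 18 rose and 1 fell, also when adjusted over the list alone (median 2.84, camera adjusted p = 8.74e-07, adjusted p = 0.343 with an estimated correlation). Serpinb2, an inhibitor of plasminogen activators, changed by 5.87 (SE 1.28, adjusted p = 0.00571); its call was lost without sham library A (adjusted p = 0.106) or B (0.0845) and with limma-voom (0.125). Of 24 genes of the inflammasome and programmed cell death, 13 rose and 1 fell, also when adjusted over the list alone (median 1.16, camera adjusted p = 0.000394, adjusted p = 0.343 with an estimated correlation). Nlrp3, an inflammasome sensor, changed by 5.33 (SE 0.75, adjusted p = 0.000785). The inflammasome count was 8 without sham library A, and the list lost its call without MI library A (adjusted p = 0.119).

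Immediate early genes and long noncoding RNAs rose as well. Of 25 immediate early genes, 16 rose (18 adjusted over the list alone; median 1.97, camera adjusted p = 0.00104, adjusted p = 0.634 with an estimated correlation). Egr1, a transcription factor of this class, rose from 3.67 ± 0.470 to 119.6 ± 84.6 CPM, or 5.04 (SE 1.31, adjusted p = 0.0150). The immediate early count was 7, 5 and 6 without sham library A, sham library B and MI library A, and the list lost its call without MI library A (adjusted p = 0.364) and with fry (0.0990). Egr1 lost its call without each of the 4 libraries of 1 day (adjusted p = 0.112, 0.115, 0.152 and 0.0758 without sham A, sham B, MI A and MI B), with limma-voom (0.109) and without the low-count filter (0.0616). Of 15 long noncoding RNAs, 9 rose (10 adjusted over the list alone; median 1.93, camera adjusted p = 0.000151, adjusted p = 0.343 with an estimated correlation). Mir22hg, the host transcript of a microRNA, changed by 3.74 (SE 0.50, adjusted p = 0.000651). Of 18 markers of quiescent fibroblasts, 9 fell, also when adjusted over the list alone (median −0.86, camera adjusted p = 0.00630, adjusted p = 0.634 with an estimated correlation). Htra3, a secreted protease, fell from 122 ± 0.231 to 18.1 ± 7.33 CPM. The fibroblast count was 5 without sham library A and 4 without sham library B, and the list lost its call with fry (adjusted p = 0.0948) and without both B libraries of 1 day (0.0774).

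The other main lists did not pass the camera test at 1 day, and their members moved both ways. In the glycolysis and hypoxia list, 12 of 26 genes rose and 6 fell, also when adjusted over the list alone (median 0.59, adjusted p = 0.120). Slc16a3, a lactate transporter, changed by 4.53 (SE 0.45, adjusted p = 0.000189) and Hmox1, the inducible heme oxygenase, by 3.94 (SE 0.29, adjusted p = 8.70e-05). In the list of cardiac stress and fetal genes, 9 of 19 rose and 3 fell, also when adjusted over the list alone (median 1.55, adjusted p = 0.0828). Nppb, which encodes brain natriuretic peptide, rose from 394 ± 14.7 to 2144 ± 165 CPM, or 2.45 (SE 0.31, adjusted p = 0.000482), Ankrd2 changed by 5.08 (SE 0.55, adjusted p = 0.000240) and Gdf15 by 4.40 (SE 0.62, adjusted p = 0.000816). Nppa, for atrial natriuretic peptide, stood at 376 ± 39.5 and 476 ± 147 CPM, with a log2 fold change of 0.34 (SE 0.23, adjusted p = 0.263) that became 0.53 (adjusted p = 0.0371) without MI library A and −0.0139 (adjusted p = 0.963) without MI library B. Myh7, the slow myosin heavy chain, changed by −0.90 (SE 0.27, adjusted p = 0.0274); its call was lost without sham library A (adjusted p = 0.153), sham library B (0.0591) or MI library A (0.0711) and with library size alone (0.114). Of the glycolysis genes, 2 and 3 fell without sham libraries A and B, and of the stress genes 1 fell without sham library A or B and 6 without MI library A.

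In 4 further lists the count of members was also split at 1 day. Of 35 genes of the extracellular matrix and activated fibroblasts, 11 rose and 9 fell (11 and 10 adjusted over the list alone; median 0.17, camera adjusted p = 0.596). Tnc, a matrix protein of wounds, rose from 11.9 ± 2.38 to 295 ± 11.8 CPM, Timp1, an inhibitor of metalloproteinases, changed by 3.52 (SE 0.35, adjusted p = 0.000195), and Postn, which marks activated fibroblasts, by 1.18 (SE 0.22, adjusted p = 0.00317). The collagen genes Col1a1 and Col3a1, the main fibrillar collagens, fell by 2.63 and 1.68 on the log2 scale; they were named after their values were seen. Of 31 interferon-stimulated genes, 12 rose and 4 fell, also when adjusted over the list alone (median 0.40, adjusted p = 0.103), among them Oasl1 at 2.01 (SE 0.31, adjusted p = 0.00130) and Isg15 at 1.76 (SE 0.44, adjusted p = 0.0124). Without sham library A, or without sham library B, 4 interferon-stimulated genes rose and 1 fell, and Isg15 lost its call without sham library A (adjusted p = 0.119). Of 17 markers of resident macrophages, 3 rose and 4 fell, also when adjusted over the list alone (median −0.40, adjusted p = 0.271), among them Fcna at −2.24 (SE 0.52, adjusted p = 0.00901) and Cbr2 at −1.97 (SE 0.34, adjusted p = 0.00211). The 3 resident macrophage markers that rose became 0 without sham library A, sham library B, MI library A or either MI library of 3 days, and without MI library B 2 rose and 5 fell, with a median of −1.08. Only 2 of these markers fell without sham library B, where Fcna (adjusted p = 0.0576) and Postn (0.0509) lost their calls. Of 35 genes of the cell cycle and DNA replication, 1 rose and 1 fell (1 and 0 adjusted over the list alone; median 0.06, or −0.66 without MI library B, adjusted p = 0.789). The gene that fell, Cenpf, changed by −1.13 (SE 0.38, adjusted p = 0.0422), a call lost without sham library B (adjusted p = 0.306), MI library A (0.142) or MI library B (0.0819), without either MI library of 3 days (0.0756 and 0.0762), and with 5 other settings.

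**Figure D2:**
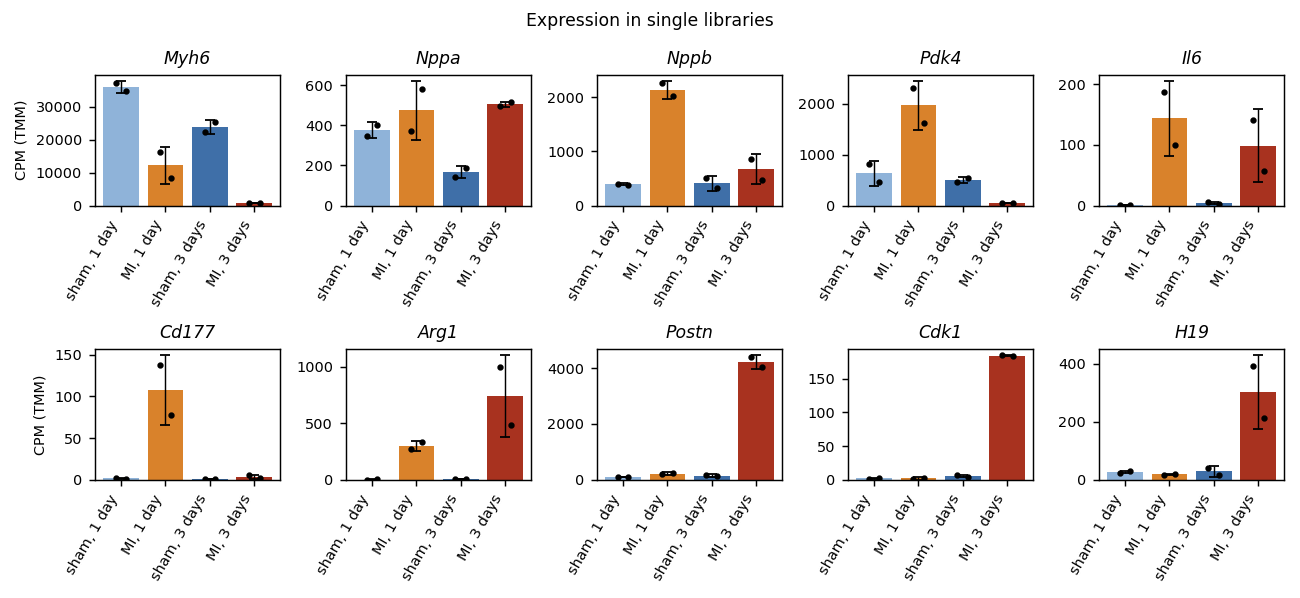
Bars show mean CPM and error bars the SD of 10 genes in the 4 groups (n = 2), with a point for each library and a separate linear axis for each gene. Myh6 fell to 663 ± 45.8 CPM in MI at 3 days, Il6 and Cd177 were highest in MI at 1 day, and Postn, Cdk1 and H19 in MI at 3 days.

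By 3 days after MI, the fall of cardiomyocyte genes was deep and genes of cell division and matrix were high. Myh6 stood at 663 ± 45.8 CPM after MI against 23788 ± 2082 after sham surgery, a log2 fold change of −5.16 (SE 0.34, adjusted p = 2.87e-06). Cdk1, the kinase that drives mitosis (Ensembl ENSMUSG00000019942, chromosome 10, 69335146 to 69352912 in GRCm38.p6), rose from 5.73 ± 1.57 to 184 ± 0.842 CPM, a fitted rise of 32.1 times (SE 0.37 on the log2 scale, adjusted p = 5.04e-06). Postn (Ensembl ENSMUSG00000027750, chromosome 3, 54359267 to 54391041 in GRCm38.p6) rose from 150.0 ± 40.5 to 4227 ± 241 CPM, a log2 fold change of 4.82 (SE 0.25, adjusted p = 1.49e-06). The largest falls were in Myh7b, at −7.06 (SE 0.51, adjusted p = 4.52e-06), and the sodium channel genes Scn4b, at −7.06 (SE 0.35, adjusted p = 1.29e-06), and Scn4a, at −6.64 (SE 0.36, adjusted p = 1.51e-06). The largest rises were in Cxcl3, Il1a and the fibrillar collagen gene Col11a1, the last at 6.93 (SE 0.75, adjusted p = 3.23e-05). Cxcl3 had 2 counts in the sham libraries and 1609 in the MI libraries, a ratio of 561 with a counting interval from 155 to 4640.0, and lost its call with limma-voom (adjusted p = 0.161). Il1a, an inflammatory cytokine, stood at 7.15 (SE 1.82, adjusted p = 0.00547), at 1.85 without MI library A (adjusted p = 0.229), and lost its call without sham library A (0.0760) or B (0.0783), without MI library A of 1 day (0.0515) and with limma-voom (0.452).

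By the edgeR quasi-likelihood test, 4912 genes rose and 3679 fell among 15508 tested at 3 days (Benjamini-Hochberg adjusted p, threshold 0.05), of which 3688 rose and 2863 fell by at least 2-fold. Library size alone gave 6052 rises and 3020 falls, and the 4 libraries of 3 days alone 4373 rises and 4781 falls. Falls also outnumbered rises without MI library A of 1 day or either MI library of 3 days. The median of all genes moved by 0.26 on the log2 scale with library size alone, by −0.13 with DESeq2's size factors and by −0.13 with the DESeq2 Wald test.

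All 25 sarcomere genes and all 27 genes of calcium handling and ion channels fell at 3 days, also when adjusted over each list alone. Their medians were −3.56 and −3.72, and Kcnip2 changed by −6.05 (SE 0.37, adjusted p = 2.19e-06). Camera adjusted p was 8.69e-16 for each, and with an estimated correlation adjusted p = 0.171 and adjusted p = 0.0628. All 28 genes of fatty acid uptake and oxidation, 50 of 51 respiratory chain genes and all 23 genes of the citric acid cycle and pyruvate dehydrogenase fell, with the same counts adjusted over the list alone. Their medians were −3.24, −2.16 and −2.37. Plin5, a lipid droplet protein of oxidative muscle, changed by −5.27 (SE 0.22, adjusted p = 1.26e-06) and Ppara by −4.87 (SE 0.41, adjusted p = 9.33e-06). Cox6a2 and Cox7a1, the muscle forms of cytochrome c oxidase subunits, changed by −4.32 (SE 0.19) and −4.31 (SE 0.18), Ogdh by −3.82 (SE 0.23) and Idh2 by −3.79 (SE 0.24). By camera the 3 lists had adjusted p = 6.04e-17, 4.87e-21 and 6.47e-14, and with an estimated correlation adjusted p = 0.171, 0.208 and 0.208. Of 25 cardiac transcription factors and mitochondrial regulators, 24 fell and 1 rose, also when adjusted over the list alone (median −2.69, camera adjusted p = 9.77e-11, adjusted p = 0.171 with an estimated correlation), with Esrrb, a nuclear receptor, at −5.15 (SE 0.25, adjusted p = 1.26e-06). The mitochondrial share of transcript-table reads in the same MI libraries was 6.51% and 4.19%, against 16.6% and 15.7% in sham.

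All 35 genes of the cell cycle and DNA replication rose at 3 days, also when adjusted over the list alone (median 3.87). Ccnb1, the cyclin partner of Cdk1, changed by 5.18 (SE 0.44, adjusted p = 6.91e-06). Of 35 genes of the extracellular matrix and activated fibroblasts, 32 rose, also when adjusted over the list alone (median 2.60). Cthrc1, a secreted protein of activated fibroblasts, rose from 3.04 ± 0.891 to 136 ± 5.06 CPM, or 5.48 (SE 0.29, adjusted p = 1.26e-06), and Tnc changed by 5.37 (SE 0.43, adjusted p = 7.11e-06). By camera adjusted p was 8.38e-12 for the cell cycle and 9.77e-11 for the matrix, and with an estimated correlation adjusted p = 0.260 and adjusted p = 0.208.

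All 25 markers of monocytes and recruited macrophages rose at 3 days, also when adjusted over the list alone (median 4.01). Spp1, the gene of osteopontin, rose from 39.8 ± 1.69 to 4219 ± 825 CPM, or 6.73 (SE 0.52, adjusted p = 6.24e-06), and Arg1 changed by 6.39 (SE 0.54, adjusted p = 9.82e-06). Of 36 cytokine and chemokine genes, 28 rose, and of 24 neutrophil markers, 19 rose, with the same counts adjusted over the list alone. The medians were 3.55 and 2.60, or 3.39 and 2.52 with 4 and 2 members of 3 counts or fewer at their bounds. Il6 changed by 4.71 (SE 0.53, adjusted p = 4.77e-05), and the C-type lectin genes Clec4d and Clec4e by 4.74 (SE 0.26, adjusted p = 1.51e-06) and 4.48 (SE 0.53, adjusted p = 8.21e-05). Camera adjusted p was 9.19e-10, 2.63e-06 and 7.94e-05 for monocyte markers, cytokines and neutrophil markers, and with an estimated correlation adjusted p = 0.253, 0.389 and 0.531. The neutrophil count was 12 without sham library B.

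Interferon-stimulated genes and genes of cell death rose at 3 days. Of 31 interferon-stimulated genes, 23 rose (24 adjusted over the list alone; median 1.24, camera adjusted p = 0.000147, adjusted p = 0.479 with an estimated correlation), and 13 rose without MI library B. Mx1, an antiviral protein, changed by 3.58 (SE 0.43, adjusted p = 8.59e-05) and Zbp1, a nucleic acid sensor, by 2.40 (SE 0.35, adjusted p = 0.000271). Of 24 genes of the inflammasome and programmed cell death, 21 rose (22 adjusted over the list alone; camera adjusted p = 1.41e-06, adjusted p = 0.208 with an estimated correlation). Of 22 matrix metalloproteinases and genes of the plasminogen system, 16 rose and 2 fell (16 and 3 adjusted over the list alone; median 2.79, camera adjusted p = 0.00289, adjusted p = 0.338 with an estimated correlation). Mmp12, the macrophage elastase, rose from 2.21 ± 0.274 to 172 ± 62.9 CPM. Of 15 long noncoding RNAs, 12 rose and 2 fell, also when adjusted over the list alone (median 1.98, camera adjusted p = 0.00409, adjusted p = 0.208 with an estimated correlation), with the imprinted H19 at 3.40 (SE 0.45, adjusted p = 0.000148). Of 16 genes of dendritic cells and MHC class II, 7 rose and 1 fell (11 and 1 adjusted over the list alone; median 1.53, camera adjusted p = 0.0130, adjusted p = 0.338 with an estimated correlation), with Fscn1, an actin-bundling protein, at 3.00 (SE 0.29, adjusted p = 2.29e-05); without sham library A, 11 rose. Of 7 adipocyte markers 3 fell, also when adjusted over the list alone (median −2.70, or −1.84 with 2 members at their bounds, camera adjusted p = 0.01003, adjusted p = 0.317 with an estimated correlation), with Thrsp at −3.67 (SE 0.21, adjusted p = 1.82e-06). The adipocyte call was lost without sham library A of 1 day (adjusted p = 0.0568), sham library B of 1 day (0.0527), MI library A of 1 day (0.0857), sham library A (0.118), MI library A (0.0965) or MI library B (0.156) of 3 days, and 5 markers fell without MI library A of 1 day.

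In 3 main lists members moved both ways at 3 days, and the camera test did not pass. Of 26 glycolysis and hypoxia genes, 11 rose and 7 fell, also when adjusted over the list alone (median 0.34, adjusted p = 0.576), with Hmox1 at 4.85 (SE 0.30, adjusted p = 2.44e-06) and Slc16a3 at 3.40 (SE 0.42, adjusted p = 0.000105). Of 19 cardiac stress and fetal genes, 5 rose and 6 fell (6 and 6 adjusted over the list alone; adjusted p = 0.842), with a median of 0.13 but a mean of −0.06, the direction of the test. Nppa rose from 165 ± 30.2 to 505 ± 13.6 CPM, or 1.61 (SE 0.23, adjusted p = 0.000285), and Myh7 and Xirp1, a protein of the intercalated disc, changed by −3.66 (SE 0.30, adjusted p = 8.76e-06) and −2.28 (SE 0.31, adjusted p = 0.000205). Nppb stood at 412 ± 135 and 673 ± 273 CPM, with a log2 fold change of 0.71 (SE 0.29, adjusted p = 0.0645); adjusted p was 0.0165 with library size alone, 0.0486 with a filter of 1 CPM and 0.0388 without sham library A. Of 17 markers of resident macrophages, 5 rose and 7 fell, also when adjusted over the list alone (median −0.64, adjusted p = 0.429), with Lyve1 at −2.39 (SE 0.28, adjusted p = 8.16e-05) and Mgl2 at −2.26 (SE 0.40, adjusted p = 0.00101). The 11 glycolysis rises were 7 without sham library A and 5 without MI library A, and the 7 falls were 4 without either sham library or MI library B. The 5 stress rises were 3, 2 and 3 without sham library B, MI library A and MI library B. The 5 resident macrophage rises were 3 without MI library A of 1 day, MI library A or MI library B, and 2 without sham library B, and the 7 falls were 3 and 4 without sham library A and MI library A.

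**Figure D3:**
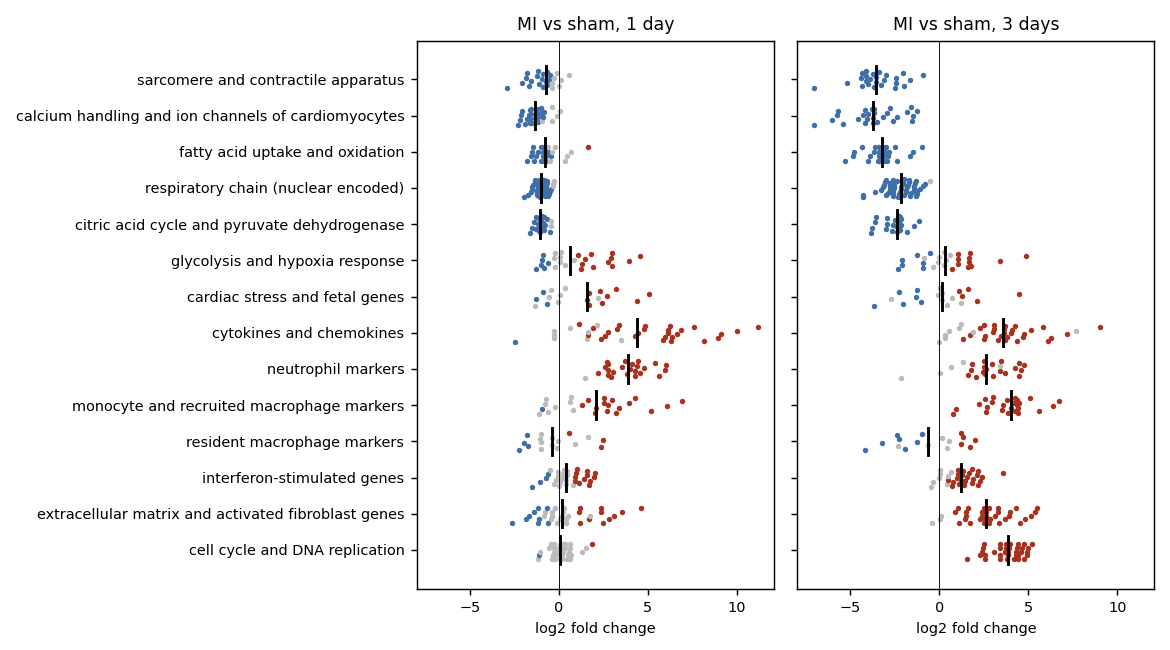
Each point is a gene of 1 of 14 lists, placed by its log2 fold change of MI against sham at 1 day (left) and 3 days (right); red points rose, blue points fell, grey points did not pass the test, and black bars are list medians. The median of the cell cycle list was 0.06 at 1 day (−0.66 without MI library B) and 3.87 at 3 days, and that of the sarcomere list −0.74 and −3.56.

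The difference between the effects of MI at 3 days and at 1 day was tested in the same fit. It asks which responses to MI differed between the time points. The effect on cell cycle and matrix genes was more positive at 3 days, and that on cardiomyocyte genes more negative. Cdk1 differed by 5.31 (SE 0.72, adjusted p = 0.00113), Postn by 3.63 (SE 0.32, adjusted p = 0.000150) and Myh6 by −3.61 (SE 0.41, adjusted p = 0.000447), each as the log2 fold change at 3 days minus that at 1 day. Il6 differed by −4.23 (SE 1.13, adjusted p = 0.0225) and Cd177 by −4.11 (SE 1.06, adjusted p = 0.0204). Il6 stood at 3.76 ± 1.71 CPM in sham and 98.8 ± 59.9 CPM in MI at 3 days, against 0.288 ± 0.162 and 144 ± 61.8 CPM at 1 day, and Cd177 stood at 0.986 ± 0.118 and 3.62 ± 2.66 CPM at 3 days. Pdk4 rose at 1 day and fell at 3 days, where it stood at 47.5 ± 2.83 CPM against 501 ± 58.9 in sham, a difference of −5.03 (SE 0.41, adjusted p = 0.000118). The 5 most negative differences were those of Ngp, a granule protein of neutrophils, at −7.53 (SE 2.01, adjusted p = 0.0234), Scd4, at −6.83 (SE 0.70, adjusted p = 0.000291), the calcium channel gene Cacna1s, at −5.75 (SE 0.44, adjusted p = 0.000111), Ucp3, a mitochondrial uncoupling protein, at −5.49 (SE 0.59, adjusted p = 0.000370), and Scn4b, at −5.44 (SE 0.45, adjusted p = 0.000118). The 5 most positive were those of the histone genes Hist1h2af, at 8.34 (SE 0.69, adjusted p = 0.000105), Hist1h3g, at 8.18 (SE 1.08, adjusted p = 0.000672), Hist1h2bm, at 8.04 (SE 0.85, adjusted p = 0.000223), Hist1h2ae, at 7.72 (SE 0.92, adjusted p = 0.000354), and Hist1h3h, at 7.34 (SE 0.82, adjusted p = 0.000318). Histone genes have near-identical copies in the genome and Scd4 has related genes of its family, so the values of single genes are uncertain. Hist1h3g had 2 counts in MI at 1 day, so its fitted value is not an exact fold. Ngp lost its call without sham library A (adjusted p = 0.108) or B (0.0963) of 1 day, without any of the libraries of 3 days (0.0792 to 0.217), with limma-voom (0.119) and without the low-count filter (0.0620).

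By the edgeR quasi-likelihood test 2046 genes had a more positive and 1753 a more negative effect at 3 days (Benjamini-Hochberg adjusted p, threshold 0.05). Their number, 3799, was 1958 without sham library A and 1582 without sham library B of 1 day, and 2103, 1829 and 1575 without sham library B, MI library A and MI library B of 3 days. The balance turned with DESeq2's size factors, to 1793 more positive and 1958 more negative effects, and with the DESeq2 Wald test, to 1935 and 2084. In the other planned settings with all 8 libraries more effects stayed positive, as with library size alone (1945 and 1830). The balance also turned to more negative effects without MI library A of 1 day or either MI library of 3 days. Across the 15508 genes, which are not independent replicates, the fold changes of both days had a Pearson correlation of 0.519 and a Spearman correlation of 0.541. Of 4214 genes called on both days, 3879 kept their direction: 1816 rose on both days, against 948 expected of independent lists, and 2063 fell on both days, against 725 expected. Another 257 fell at 1 day and rose at 3 days, against 969 expected, and 78 rose and then fell, against 710.0 expected.

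Among the fixed lists, the camera test of the difference passed for 15. Of 35 cell cycle genes, 32 had a more positive effect at 3 days (35 adjusted over the list alone), as did 28 of 35 matrix genes (29), 15 of 25 monocyte markers (16), 7 of 31 interferon-stimulated genes (7) and 6 of 24 inflammasome genes (6). Camera adjusted p was 9.02e-17, 1.67e-13, 6.94e-05, 0.00651 and 0.00298 in this order, and with an estimated correlation adjusted p = 0.279, 0.242, 0.506, 0.776 and 0.456. The effect was more negative at 3 days for 24 of 25 sarcomere genes (25 adjusted over the list alone), 23 of 27 genes of calcium handling and ion channels (24), 26 of 28 genes of fatty acid oxidation (28), 37 of 51 respiratory chain genes (41), 21 of 23 genes of the citric acid cycle (21) and 15 of 25 cardiac transcription factors (18). Their camera adjusted p was 2.12e-16, 4.31e-13, 3.01e-17, 4.31e-13, 6.33e-11 and 1.07e-07, and with an estimated correlation adjusted p = 0.202, 0.0930, 0.199, 0.415, 0.326 and 0.242. For 9 of 19 stress genes the effect was more negative and for 2 more positive (10 and 3 adjusted over the list alone), and it was more negative for 4 of 24 neutrophil markers (3), 4 of 25 immediate early genes (4) and 3 of 7 adipocyte markers (3). Their camera adjusted p was 0.0208, 0.0411, 0.00477 and 0.0310, and with an estimated correlation adjusted p = 0.456, 0.882, 0.882 and 0.456.

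Several of these differences changed when 1 library was left out. This leaves 1 library in its group and fewer degrees of freedom. Lost power and a trait of the library removed cannot be told apart in such fits. The respiratory chain count was 14 and 15 without sham libraries A and B of 1 day, 22 without either sham library of 3 days and 20 without MI library B of 3 days. The citric acid cycle count was 11 without either sham library of 1 day. The monocyte count was 8 without sham library B of 1 day and 9 without MI library B of 3 days. The interferon count was 2 without sham library A of 1 day, MI library A or MI library B of 3 days, and 12 without sham library A of 3 days, and the list lost its call with fry (adjusted p = 0.133). The inflammasome count was 2 without sham library B of 1 day, MI library A or MI library B of 3 days. The stress list lost its call without sham library B (adjusted p = 0.0510) or MI library A (0.437) of 1 day, and without sham library A (0.0712) or MI library B (0.0656) of 3 days. The neutrophil list lost it without sham library B (0.325) or MI library A (0.742) of 1 day, sham library A (0.395) or MI library B (0.461) of 3 days, with fry (0.408) and with DESeq2's size factors (0.0512). The immediate early list lost it without MI library A of 1 day (0.742), sham library A (0.118) or MI library B (0.136) of 3 days, and with fry (0.347). The adipocyte list lost it without sham library B (0.0705) or MI library B (0.234) of 1 day, and without sham library A (0.0912), MI library A (0.0740) or MI library B (0.135) of 3 days. The neutrophil count was 1 without sham library A of 1 day, sham library B or MI library B of 3 days, and 0 without sham library B of 1 day or sham library A of 3 days. The immediate early count was 1, 0, 2 and 12 without sham A, sham B, MI A and MI B of 1 day, and 0, 2, 9 and 1 without those of 3 days. The adipocyte count was 1 without sham library B of 1 day, as was the number of stress genes with a more positive effect, also without either MI library of 3 days.

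**Figure D4:**
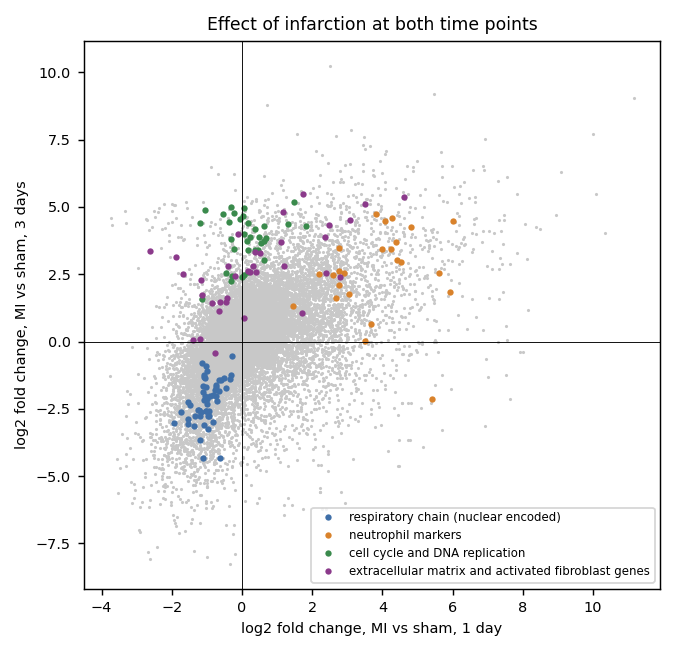
Each point is 1 of 15508 genes, placed by its log2 fold change of MI against sham at 1 day (horizontal) and at 3 days (vertical), with the genes of 4 lists in colour. The cell cycle genes had medians of 0.06 (−0.66 without MI library B of 1 day) and 3.87, and the respiratory chain genes −1.02 and −2.16.

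Infarcted ventricles of 3 days were also compared with those of 1 day, and sham ventricles likewise. Each time point has its own count table, so that time and any batch of the tables cannot be told apart. After MI, Hist1h2af rose by 8.57 (SE 0.48, adjusted p = 4.75e-06) and Hist1h3d by 8.09 (SE 0.72, adjusted p = 1.34e-05) from 1 to 3 days. Hist1h3g had 2 counts at 1 day and 2338 at 3 days, a ratio of 445 with a counting interval from 123 to 3675; histone genes have near-identical copies, so single values are uncertain. The largest falls were those of Ngp, at −7.01 (SE 1.09, adjusted p = 0.000726), Scd4, at −6.49 (SE 0.56, adjusted p = 2.53e-05), and Scn4b, at −5.71 (SE 0.37, adjusted p = 7.42e-06). By edgeR's quasi-likelihood test 3631 genes rose and 3411 fell (Benjamini-Hochberg adjusted p), with 4420 and 2855 by library size alone, 3216 and 3837 by DESeq2's size factors, and 3607 and 5821 without MI library A of 1 day. Their number, 7042, was 4517 without MI library A and 4037 without MI library B of 3 days. Between the sham groups, edgeR called 0 genes, with 1211 at an unadjusted p under 0.05. In the same comparison limma-voom called 0 genes and the DESeq2 Wald test 60, of which 20 were higher and 40 lower at 3 days. Without either MI library of 1 day edgeR called 2 genes, and without sham library A of 3 days 1.

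The transcript tables, summed to genes, gave a separate view of the same libraries and hold the 13 protein-coding genes of mitochondrial DNA. All 13 rose at 1 day and all 13 fell at 3 days. The median log2 fold change was 2.25 at 1 day, from 1.22 for mt-Nd3 to 2.60 for mt-Nd6, both subunits of complex I. At 3 days the median was −1.93, from −2.26 for mt-Co2, a subunit of cytochrome c oxidase, to −1.45 for mt-Nd3. All 13 effects differed between the days, with a median difference of −4.21. At 1 day, 9 rose without MI library B (median 1.52) and 10 without sham library A or B, and at 3 days 11 fell without MI library B.

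In these tables, 2453 genes rose and 2915 fell at 1 day among 14571 tested with edgeR, and 4530 rose and 3336 fell at 3 days. The largest falls at 1 day were those of Dnajc28, at −4.56 (SE 0.35, adjusted p = 7.34e-05), Lrtm1, at −4.49 (SE 0.33, adjusted p = 6.30e-05), and Lrrc14b, at −3.90 (SE 0.49, adjusted p = 0.000362), and the largest rises those of Cxcl3, Cxcl2 and Il6, the last at 8.31 (SE 0.80, adjusted p = 0.000156). At 3 days the largest rises were those of Cxcl3, Il1a and Spp1, the last at 6.76 (SE 0.63, adjusted p = 1.23e-05), and the largest falls those of Myh7b, at −6.53 (SE 0.46, adjusted p = 2.54e-06), Scn4b, at −6.49 (SE 0.37, adjusted p = 1.33e-06), and Dnajc28, at −6.47 (SE 0.38, adjusted p = 1.33e-06). The effect was more positive at 3 days for 1952 genes and more negative for 1502, with Scd4, Ucp3 and Timp4 (−6.40, −5.66 and −5.51) at the lower end. At the upper end were the histone genes Hist1h3g, Hist1h2ah and Hist1h2bl, whose means in MI at 1 day were 0.0615, 0.164 and 0.0810 CPM, too low for an exact fold. Of 13536 genes tested in both kinds of table, 4669 were called in both at 1 day, 7255 at 3 days and 2954 for the difference, and 4669, 7253 and 2954 of them had the same sign. The 1-day count of 5368 was 2657 without sham library A and 2859 without sham library B. The count of differences, 3454, was 2150, 1706, 2146, 2083 and 1907 without sham A of 1 day, sham B of 1 day, sham B of 3 days, MI A of 3 days and MI B of 3 days. With library sizes from the transcript tables, 2928 genes rose and 2775 fell at 1 day, 3836 rose and 4155 fell at 3 days, and 1489 differences were positive and 2416 negative, 38.1% against 56.5% upward.

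The deposited DESeq2 table of 1 day gave adjusted p under 0.05 to 1641 genes with a positive and 2104 with a negative log2 fold change, and Myh6 stood at −1.53 (SE 0.32) and Postn at 1.09 (SE 0.27) in it. In the table of 3 days, Myh6 stood at 5.32 (SE 0.17) and Postn at −4.60 (SE 0.25), so that its sign is sham over MI, and 4397 genes were positive and 4296 negative. With that sign turned, the 3640 genes called both there and by edgeR at 1 day, and the 7875 at 3 days, had the same direction. The deposited transcript tests gave an adjusted p under 0.05 to 1900 transcripts with a positive and 2157 with a negative fold change, of 96535, at 1 day. At 3 days these were 6663 and 5426. The direction of this sign was not checked against the counts, so rises and falls after MI cannot be read from it.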

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

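The tests of deeper sequencing, of receptor expression and of the mitochondrial share were chosen only after the results were seen; that of read number against transcript length and that of a common factor were set beforehand.

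Effects of MI that differed between 3 days and 1 day are listed here, each as the later minus the earlier effect on the log2 scale, by the edgeR or camera test of the difference itself. In all, 3799 genes of the count tables and 3454 genes of the transcript tables differed. Among lists, the medians of those more negative at 3 days were −2.60 for the sarcomere, −2.16 for calcium handling and ion channels, −2.30 for fatty acid oxidation, −1.16 for the respiratory chain, −1.46 for the citric acid cycle, −1.74 for stress genes, −0.69 for neutrophil markers, −1.41 for immediate early genes, −2.06 for cardiac transcription factors and −1.51 for adipocyte markers. Those more positive were 1.86 for monocyte markers, 0.72 for interferon-stimulated genes, 2.19 for the extracellular matrix, 3.58 for the cell cycle and 0.67 for the inflammasome list. With an estimated correlation, none of the 15 lists passed (0 calls). The mitochondrially encoded genes had a median difference of −4.21.

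Among named genes of muscle and ion channels, differences were −3.61 for Myh6, −2.76 for Myh7, −4.15 for Myh7b, −2.02 for Mylk3, −1.22 for Asb2, −3.72 for Kcnip2, −3.21 for Kcnj11, −5.44 for Scn4b, −4.70 for Scn4a, −5.75 for Cacna1s and −3.99 for Xirp1. Among genes of metabolism they were −3.08 for Ppara, −5.03 for Pdk4, −4.27 for Plin5, −1.08 for Ndufs7, −3.69 for Cox6a2, −3.19 for Cox7a1, −1.29 for Dlat, −2.29 for Ogdh, −2.93 for Idh2, −5.49 for Ucp3, −2.70 for Perm1, −3.78 for Esrrb, −2.20 for Thrsp and −6.83 for Scd4. Among genes of inflammation and stress they were −4.23 for Il6, −4.11 for Cd177, −7.53 for Ngp, 2.78 for Spp1, −2.30 for Lyve1, 2.38 for Fscn1, 1.27 for Nppa and −1.74 for Nppb. Levels of Il6 at 1 and 3 days were 0.288 ± 0.162 and 3.76 ± 1.71 CPM in sham. In MI they were 144 ± 61.8 and 98.8 ± 59.9 CPM, so its difference lay largely in the sham groups. Among long noncoding RNAs the differences were −2.52 for Mir22hg and 3.91 for H19. Among genes of matrix and division the differences were 3.63 for Postn, 1.61 for Timp1, 4.66 for Col11a1, 3.73 for Cthrc1, 5.31 for Cdk1, 2.70 for Cenpf, 8.18 for Hist1h3g, 8.34 for Hist1h2af, 6.79 for Hist1h3d, 8.04 for Hist1h2bm, 7.72 for Hist1h2ae and 7.34 for Hist1h3h. Hist1h3g had 2 counts in MI at 1 day, so its fitted value is no bound.

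MI library B at 1 day held reads for 92.0% of 1495 chemosensory receptor genes. Deeper sequencing was excluded, since its total was 0.369 of the median of the 8 libraries. Receptor genes together held 1010 CPM of the gene counts in MI library B and 81.6 CPM in MI library A. Sham libraries A and B of 1 day held 47.2 and 113 CPM. These values argue against receptor expression as a response to MI of the same size in both MI libraries. A smaller common response at 1 day stayed open. MI library A held 0.720 of the share of gene counts in receptor genes of the higher sham library (B) but 1.73 times that of sham library A. In MI library A 23.5% of receptor genes had reads, against 50.6% and 5.22% in sham libraries B and A. Reads from genomic DNA stayed open: the Spearman correlation between reads and transcript length was 0.215 across 1449 receptor genes, between the bounds of 0.1 and 0.3 set beforehand, against 0.0438 to 0.161 in the other 7 libraries.

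Mitochondrially encoded genes took 28.7% and 43.3% of the transcript-table reads in the MI libraries A and B at 1 day, against 15.0% and 13.9% in sham. Reads from genomic DNA stay open as the source in libraries A and B, since no value separates mitochondrial DNA from RNA. Library A held 0.647 of the share of receptor reads in sham library B of 1 day, the sham library with the most. In transcript-table reads this was 56.1 against 86.8 CPM, but sham library A of 1 day stood at 17.7 CPM. Sham libraries A and B of 3 days stood at 21.3 and 30.2 CPM. Library B held 6.83 times the share in sham library B of 1 day. Receptor reads do not measure mitochondrial DNA, so these ratios cannot decide the question for either library. A loss of nuclear-encoded RNA alone also stays open: the median of the mitochondrially encoded genes lay 3.27 above that of the respiratory chain list on the log2 scale, but shares of a library cannot show which of them moved. An effect of MI on mitochondrial RNA itself stays open too. All 13 mitochondrially encoded genes rose at 1 day in the test of MI against sham, but that test counts reads and cannot separate these sources.

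Cardiomyocyte genes fell at 3 days in the lists of the sarcomere, calcium handling and ion channels, fatty acid oxidation, the respiratory chain and the citric acid cycle, with medians from −3.72 to −2.16. The spread of the falls argues against dilution of cardiomyocyte RNA by that of other cells, with 1 common factor for all genes, as the whole cause. The SD of the log2 fold changes over the 25 sarcomere genes was 5.65 times the median SE of a gene, 0.221, where the bound set beforehand was 2. The test cannot judge dilution that lowers genes unequally, as where other cells express some of them. Such dilution, dilution in part, death of cardiomyocytes and regulation in surviving cells stay open and could not be separated in RNA of the whole tissue.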

How the results depend on the processing

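The settings chosen after the data were seen left out both B libraries of day 1 or, in the transcript tables, the mitochondrially encoded genes; all others were planned. With 1 library left out up to 3 of 6051 called genes at 1 day, 2 of 8591 at 3 days and 9 of 7042 for MI at 3 days against 1 day turned sign, and 0 in all other settings. Over 1649 alternatives for named genes, 1592 kept direction and side of the threshold, 52 lost their call, 4 gained one and 1 reversed at 1 day: −0.0139 (adjusted p = 0.963) for Nppa without MI library B, against 0.53 (0.0371) without MI library A. Of 564 alternatives for called lists 487 kept the call; 46 of the 77 losses came from the estimated correlation, which left 0 calls of 14, 17 and 15 lists, 5 from fry and 26 from others. Of 158 alternative counts, 133 lay within 1.5 times the main value. Single transcripts gave 12366 calls at 3 days in place of 7866 genes, and DESeq2 called 60 genes between sham groups in place of 0; the causes of these and the next differences were not tested. Leaving out 1 library gave 2688 to 9388 genes at 1 day, 6031 to 9803 at 3 days, 1575 to 5297 for the difference, 4037 to 9428 for MI at 3 days against 1 day and 0 to 2 for sham. In the transcript tables the ranges were 2657 to 6821, 5874 to 9125 and 1706 to 4200. The number of called lists ranged from 14 to 17, 16 to 19 and 12 to 16. Without both B libraries of day 1, 4190 genes were called at 1 day, with 3785 of the 6051 main calls kept, 3347 for the difference, and 17 lists at 1 day. This setting ended the 1-day calls of the quiescent fibroblast list (adjusted p = 0.0774), Cxcl2 (0.1001), Fcna (0.0777), Isg15 (0.0771), Cenpf (0.222), Serpinb2 (0.0778), Egr1 (0.165), Myh7 (0.0598) and Postn (0.0519). Without mitochondrially encoded genes the transcript tables gave 5739 calls at 1 day. Leaving mitochondrially encoded genes out of the count tables was not run, since they hold none. Other median shifts over 0.1 were 0.18 and 0.19 for 3 days against 1 day in MI and sham with library size alone, −0.11 in MI with DESeq2's size factors, −0.23 at 3 days with the 4 libraries of that day, and 0.11 and 0.14 for the difference and for MI at 3 days against 1 day without the filter. Without MI library A of 1 day they were −0.22 at 3 days and −0.13 for the difference. Without MI library A or B of 3 days they were −0.21 and −0.23 at 3 days, −0.17 and −0.19 for the difference, and −0.12 and −0.14 for MI at 3 days against 1 day. No paired analysis was possible because the count columns carry no replicate numbers. Depth limits genes near 3 counts, 0.102 to 0.369 CPM, most in MI library B at 1 day.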

Other observations

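The histone set and the genes that changed direction were chosen only after the results were seen.

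Genes that moved in opposite directions on the 2 days included fibrillar collagens. Of the 257 genes that fell at 1 day and rose at 3 days, 17 were in the fixed lists. Most of these 17 lost a call when some single library was left out. Col1a1 fell at 1 day, at −2.63 (SE 0.26, adjusted p = 0.000182), and rose at 3 days, at 3.37 (SE 0.25, adjusted p = 5.03e-06). Col1a2 stood at −1.88 (SE 0.23, adjusted p = 0.000464) and 3.14 (SE 0.24, adjusted p = 5.60e-06), Col3a1 at −1.68 (SE 0.26, adjusted p = 0.00126) and 2.53 (SE 0.27, adjusted p = 3.87e-05), and Col5a1 at −1.17 (SE 0.21, adjusted p = 0.00276) and 2.29 (SE 0.21, adjusted p = 1.65e-05). Serpinh1, a chaperone of collagen folding, stood at −1.14 (SE 0.18, adjusted p = 0.00125) and 1.71 (SE 0.18, adjusted p = 3.56e-05). These 5 genes kept both calls with each library left out, with DESeq2's size factors and with library size alone. Of the 78 genes that rose and then fell, 6 were in the lists, among them Pdk4, Xirp1 and Flnc, a filamin of muscle that stood at 1.66 (SE 0.23, adjusted p = 0.000753) at 1 day. Without sham library B of 3 days Flnc lost 1 of its calls, as did Xirp1 without sham library B of 1 day. The other members, Hspb1, Malat1 and Retnla, each lost a call without any 1 of several libraries, and Retnla also with DESeq2's size factors.

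Histone genes were counted as a set without a list test. Of 57 genes with histone symbols, 35 fell at 1 day (median −1.74) and 56 rose at 3 days (median 4.22), while 1 fell. At 3 days against 1 day after MI, 56 rose (median 5.78), and between the sham groups edgeR called 0. At 1 day 22 fell without sham library A, 9 without sham library B and 27 with library size alone. The copies are near-identical, so counts of single histone genes are uncertain.

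The lists given here did not pass the camera test on the day given. Of 22 endothelial markers 7 rose and 2 fell at 1 day and 5 rose and 5 fell at 3 days (7 and 2, and 5 and 4, adjusted over the list alone). Of 18 pericyte and smooth muscle markers 1 rose and 4 fell at 1 day, and 5 rose and 9 fell at 3 days, with the same counts adjusted over the list alone. Of 18 quiescent fibroblast markers 4 rose and 9 fell at 3 days, and of 11 atrial cardiomyocyte markers 1 rose and 4 fell at 1 day and 4 rose and 4 fell at 3 days, with the same counts adjusted over the list alone. Of 20 genes of the unfolded protein response 7 rose and 1 fell at 1 day and 12 rose and 2 fell at 3 days, and of 16 heat shock genes 4 rose and 9 fell and then 4 rose and 5 fell, with the same counts adjusted over the list alone. The heat shock list had a median of 0.13 but a mean of −0.06 at 3 days. Of 25 immediate early genes 7 rose and 3 fell at 3 days (6 and 3 adjusted over the list alone).

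These counts moved when 1 library was left out. At 1 day the endothelial rises were 2, 1 and 4 without sham A, sham B and MI A, and the falls 0, 0, 6 and 1 without sham A, sham B, MI A and MI B. The pericyte falls were 2 without sham A, the atrial falls 8 without MI B and the atrial rises 3 without MI A. The rises of the unfolded protein response were 3 without sham B and its falls 4 without MI A, and the heat shock rises were 2 without sham A, sham B or MI A. At 3 days the endothelial rises were 3 without MI A of 1 day, sham B or MI B and 0 without MI A, and the falls 8 without MI A of 1 day and 3 without MI B. The quiescent fibroblast rises were 2 without sham A, sham B or MI A of 1 day and without sham B, MI A or MI B of 3 days. The atrial rises were 2 without sham B, MI A or MI B, and the falls 7 without MI A or MI B of 1 day. The rises of the unfolded protein response were 6 without MI A or MI B and its falls 5 without MI A of 1 day, and the heat shock rises were 2 without MI A. The immediate early rises were 4 without MI A of 1 day, 3 without sham A or sham B and 2 without MI A, and the falls 6 without MI A of 1 day and 1 without sham A.

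Markers of lymphocytes and blood cells passed in small numbers. Of 15 T and NK cell markers 2 rose at 1 day and 4 rose and 1 fell at 3 days (1, and 3 and 1, adjusted over the list alone). Of 11 B cell markers 2 rose at 1 day and 4 at 3 days (0 and 3 adjusted over the list alone). Without MI library A, 8 T and NK cell markers and 5 B cell markers rose at 1 day, 7 T and NK cell markers rose at 3 days without MI library B of 1 day, and at 1 day without MI library B, which had the most receptor reads, 1 and 0 rose. Of 16 genes of dendritic cells and MHC class II 3 rose at 1 day (1 adjusted over the list alone), and 1 without sham library A, sham library B or either MI library of 3 days. Of 11 platelet markers 2 rose at 1 day and 4 rose and 1 fell at 3 days, also when adjusted over the list alone. Of 4 red cell genes 1 rose at 1 day and 0 at 3 days, and this list was too short for camera.

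Of 12 epicardial and mesothelial markers 2 rose on each day (1 and 2 adjusted over the list alone). Of 11 Schwann cell and neuronal markers 1 rose at 1 day and 2 rose and 4 fell at 3 days (0, and 2 and 4, adjusted over the list alone), and 2 fell at 3 days without sham library B or MI library B. Of 7 adipocyte markers 2 fell at 1 day, and of 7 skeletal muscle markers 1 fell at 1 day and 2 rose and 3 fell at 3 days, with the same counts adjusted over the list alone. Leaving out MI library A of 1 day, where library B then stood for the group, gave 4 rises of adipocyte and 8 of skeletal muscle markers at 1 day, with more members tested. The adjusted p of the tested lists that did not pass camera ranged from 0.0828 to 0.817 at 1 day and from 0.0812 to 0.902 at 3 days.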
